A study of Mus musculus with 2 samples.

How the data were processed

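Single-cell RNA sequencing was done on subcutaneous tumours of Lewis lung carcinoma (LLC), a mouse lung cancer cell line that is grown in mice. One library came from mice given an IgG2a isotype antibody, called control here, and 1 from mice given an antibody against PD-1, an inhibitory receptor of T cells. The series text describes the control cells as untreated and the sample labels name the isotype antibody; the groups were taken from the sample labels. The anti-PD-1 cells were collected 7 days after treatment, per the labels, which give no such time for the control cells. The number of mice behind each library is not given in the sources used here.

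The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized, per the file headers. The labels' protocol names a 10x Genomics Flex kit, which reads RNA through gene-specific probes, and also a 3' protocol. The files list 19070 genes in each library. Cell Ranger 7.0.1 and the mouse build mm10 are named in the submitters' processing notes, and Cell Ranger 9.0.1 stands in the headers of the matrices. The deposited barcodes had at least 493 UMIs in control and 494 in anti-PD-1, so shallower barcodes were not analysed here. Probe counts depend on how well each probe binds, which bears on levels compared between genes more than on 1 gene compared between libraries.

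The control library held 8441 barcodes with 113268618 UMIs, and the anti-PD-1 library 9423 barcodes with 115407230 UMIs. Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept, which left 8395 control and 9422 anti-PD-1 cells. Scrublet, run per library, marked 0 control cells and 1 anti-PD-1 cell, so doublet calling did not work on these data; mixed clusters were kept out by their median Scrublet score instead. Scores over 0.2 were held by 0.79% of control and 3.11% of anti-PD-1 cells. Cells of both libraries were clustered together without batch integration in scanpy 1.11.5 (2000 variable genes, 40 components, 15 neighbours, Leiden resolution 1).

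The cell type markers, the gene lists and the rule for named genes were fixed before the data were examined. The thresholds of the naming rule were set after several looks at the data. A class other than LLC-like needed a mean marker log2 fold of at least 2, a lead of 0.5 over the next class and at least 3 detected markers. LLC-like clusters had to meet no such fold or lead. They were taken from the clusters left over, if at least 3 LLC markers were detected and their median UMI count, relative to the library's median, reached a set minimum. Every named cluster needed a median Scrublet score of at most 0.1, and no more markers of another class than of its own among the 10 leading genes. LLC-like clusters needed a median over cells of at least 500 UMIs per 1000000 (CPM) summed over Hmga2, Igf2bp1, Igf2bp2 and Wnt7b; these members of the fixed LLC list were picked after seeing which ones were detected. For LLC-like clusters the 10 leading genes were ranked by fold against the cells of the other named classes, and only cluster 9 had an LLC marker among them. Ranked against all other cells, the leading genes of cluster 2 held the smooth muscle marker Acta2 and those of cluster 13 the macrophage marker Gpnmb, with no LLC marker, so results of LLC-like cells were also computed without both clusters. Clusters 7, 8 and 10 had no LLC marker in that ranking either. The median CPM summed over the naming genes above was 1527.7 in cluster 13 and 1022.1 in cluster 2, against 1273.9 in cluster 9. Classes other than LLC-like had to lie below 500 CPM. Clusters that missed a threshold stayed unnamed; they held 30.9% of control and 16.6% of anti-PD-1 cells.

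UMIs were summed over the cells of a class in each library and scaled to CPM. Because each group has 1 library, no test was made and no p-value is given. Differences between the libraries cannot be separated from differences between animals or preparations, or of collection time. Exact Poisson intervals (95%) are given for CPM and log2 ratios, and exact Clopper-Pearson intervals for shares; they cover counting error only. All log2 ratios are anti-PD-1 over control. With 0 UMIs on 1 side the ratio was set against 3 counts. A list was described by the median log2 ratio of its members with at least 100 UMIs over both libraries, by its percentile among 10000 random lists matched on mean expression, and by its members above and below the class's median gene, with at least 5 measured members.

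In LLC-like cells the genes named were the 10 highest and 10 lowest log2 ratios among genes with at least 200 UMIs and at least 20 CPM in the higher library, without genes over 5 times higher in another named class of at least 50 cells. In other classes with at least 200 cells in both libraries, the 5 highest and 5 lowest were taken. Up to 4 members of each described list with the largest ratios, and a fixed set of immune, proliferation and metabolic genes, were added. No erythroid class was named, so globin genes were not left out by this rule. Some genes that the rule names are not reported here. Positions are from GENCODE vM21 on mm10, matched by Ensembl identifier.

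The ratio and list functions were tested on simulated counts for the LLC-like class, run on 11614 genes. Intervals covered the true ratio for 95.4% of genes, and genes simulated at a log2 ratio of 1 were recovered at 0.98. The simulated counts were Poisson draws, the model behind the intervals, without variation between cells or animals. They therefore check the computation only. Computation used python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. Alternatives covered cell filters, doublets, clustering, cell naming, scaling, depth thinning, member minimums and fold thresholds. In the setting called all deposited barcodes, Scrublet was run again on the unfiltered libraries and the cells it marked were left out. Their number is not reported here.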

Results

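The data were 2 libraries of single cells from LLC tumours, 1 from control mice and 1 from mice given anti-PD-1. The series describes the anti-PD-1 cells as tolerant of the antibody, so the comparison asks how tumour and surrounding cells of a treated tumour differ from those of a control tumour. The median cell had 7385 UMIs and 3664 genes in control and 8743 UMIs and 3981 genes in anti-PD-1. There were no replicates, so every difference below compares these 2 libraries.

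T cell-like cells made up a lower share of the anti-PD-1 library. They made up 4.10% of control cells (344 of 8395, 95% interval 3.68 to 4.54) and 1.72% of anti-PD-1 cells (162 of 9421, 1.47 to 2.0). Among the named immune cells alone the shares were 14.5% and 6.51%, and the difference of -2.38 percentage points was -3.87 among named cells only. Endothelial-like cells were also lower, at 1.33% against 0.45%, and neutrophil-like cells at 2.85% against 1.94%, differences of -0.89 and -0.90 percentage points. The endothelial-like difference was -0.55 with all deposited barcodes and -1.40 among named cells only, and the neutrophil-like one was -0.39 when each cell was named by its own marker score and -1.79 among named cells only. NK cell-like cells stood at 1.73% and 2.08%, with overlapping intervals, and dendritic cell-like cells at 1.32% and 1.70%. Monocyte-like cells made up 9.72% of control and 11.6% of anti-PD-1 cells, and macrophage-like cells 8.49% and 7.40%. Neither of these kept its direction: with at least 1000 genes per cell the differences were -0.28 percentage points for monocyte-like and 3.06 for macrophage-like cells. Fibroblast-like cells were 0.91% and 0.71%, a difference of -0.19 percentage points that was 21.63 when each cell was named by its own marker score. Under that naming the LLC-like difference was -0.26 instead of 17.23, so many LLC-like cells of the anti-PD-1 library may have been named fibroblast-like. Which cells changed name was not examined. Values of LLC-like cells given below under that naming therefore rest on a different set of cells. Among named cells only, the difference of 0.35 for NK cell-like cells was -0.01 and that of 0.38 for dendritic cell-like cells was 0.12.

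LLC-like cells made up 38.6% of control and 55.9% of anti-PD-1 cells, but this difference depended on whether 1 cluster was counted as LLC-like. Cluster 13 held 123 control and 2095 anti-PD-1 cells. With these counted as not LLC-like but kept in the total, the difference was -3.54 percentage points instead of 17.23. The share among the remaining cells is not given here, so a change of direction there is not shown. Counted in the same way without clusters 2 and 13, the difference was -4.75. The leading genes of these clusters against all other cells held a marker of another class and none of LLC. The difference was also negative under 4 other ways of filtering, clustering or naming the cells. With all deposited barcodes it was 10.47, and among named cells only 11.04. The LLC-like cells of the libraries lay in different clusters. Cluster 9 held 44.5% of the control LLC-like cells and 5.4% of the anti-PD-1 ones, while clusters 13 and 8 held 39.8% and 19.4% of the anti-PD-1 ones against 3.8% and 2.0% in control. A cluster mostly of 1 library may be that library and not a cell state. Unnamed clusters also differed in share: cluster 11, of low depth and led by globin genes, held 9.64% of control and 2.74% of anti-PD-1 cells, and cluster 1, which carried tumour and macrophage genes, 9.72% and 5.64%. Cluster 15, also of low depth, held 5.80% and 1.28%, and cluster 19 held 0.27% and 0.20%. Cluster 0, led by fibroblast genes such as Lum and Dcn, held more of the anti-PD-1 library, at 5.49% and 6.71%.

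**Figure D1:**
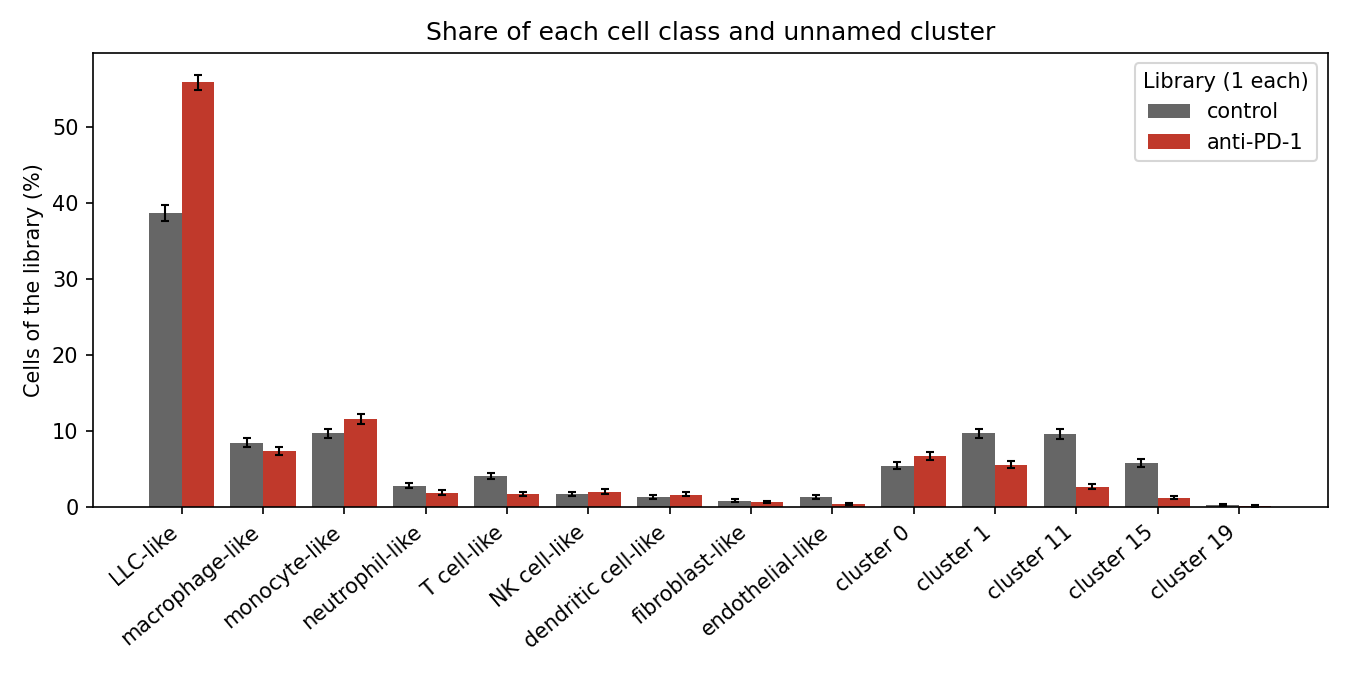
Bars give the percentage of each library's cells in each class or unnamed cluster, with exact 95% binomial intervals for counting error only. T cell-like cells stand at 4.10% in control and 1.72% in anti-PD-1, and LLC-like cells at 38.6% and 55.9%.

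In LLC-like cells, genes of the interferon gamma response, the program by which cells answer the T and NK cell cytokine interferon gamma, were lower in the anti-PD-1 library. The median log2 ratio of the list was -1.14, with 27 of 30 measured members below the class's median gene, and lay at percentile 0.00 of matched random lists. Iigp1, an interferon-inducible GTPase, was at 128 CPM in control and 30.9 in anti-PD-1 (log2 ratio -2.05, -2.12 to -1.99). Tgtp1, of the same GTPase family, had a log2 ratio of -2.72 (-2.91 to -2.53), Gbp4 of -3.31 and Gbp8 of -2.83. Ido1, which breaks down tryptophan, was at 50.7 and 16.3 CPM. The transcription factor Irf1 had a log2 ratio of -1.02 (-1.06 to -0.98). Gbp4 and Gbp8 were over 5 times higher in NK cell-like cells. Tgtp1 and the Gbp genes have close paralogs, so their values are uncertain. With each cell named by its own marker score the median of the list was -0.29, Iigp1 stood at -0.15 and Irf1 at -0.36, and over clusters 2, 7 and 10 Iigp1 stood at -1.35. Without clusters 2 and 13 the median was -0.81, and that of the type I interferon list was 0.49 instead of 0.16.

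Type I interferon genes did not share this direction over all LLC-like cells. Their median log2 ratio in LLC-like cells was 0.16, with 20 of 27 members above the median gene and percentile 98.7. The median differed between clusters, at 0.57 in cluster 8, 0.46 in cluster 13, 0.45 in cluster 7, 0.16 in cluster 2 and 0.00 in cluster 10, while in cluster 9 it was -0.16, with 20 of 27 members below the median gene. Rsad2 stood at 0.72, Ifit2 at 0.57 and Ifit3b at 0.54, while Zbp1 stood at -0.85. Without cluster 13 these genes stood at 1.21, 1.01, 1.0 and -0.48, and with thinned cells Rsad2 stood at 0.42. In cluster 10 Ifit2 was at -0.19. Of the MHC class I genes, which present antigen to CD8 T cells, 17 of 21 lay below the median gene, with a median of -0.34. The immunoproteasome gene Psmb9 stood at -1.36 and H2-Q4 at -1.25, while B2m stood at -0.18 (-0.20 to -0.16), H2-D1 at -0.21 and H2-K1 at -0.52. Cd274, which encodes the PD-1 ligand PD-L1, was at 29.4 CPM in control and 16.0 in anti-PD-1 (-0.88, -0.98 to -0.78), and was over 5 times higher in dendritic cell-like cells. With each cell named by its own marker score the MHC class I median was 0.08, Cd274 stood at 0.24 and H2-K1 at -0.21, and with the LLC-like clusters weighted equally H2-Q4 stood at -0.57. In cluster 13 Cd274 was at 0.08.

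The interferon gamma list was lower in each LLC-like cluster, with medians of -1.13 in cluster 2, -0.96 in cluster 7, which was itself led by interferon-induced genes, -0.95 in cluster 10 and -1.35 in cluster 9. In clusters 8 and 13, which had 64 and 123 control cells, the medians were -0.24 and -0.57.

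**Figure D2:**
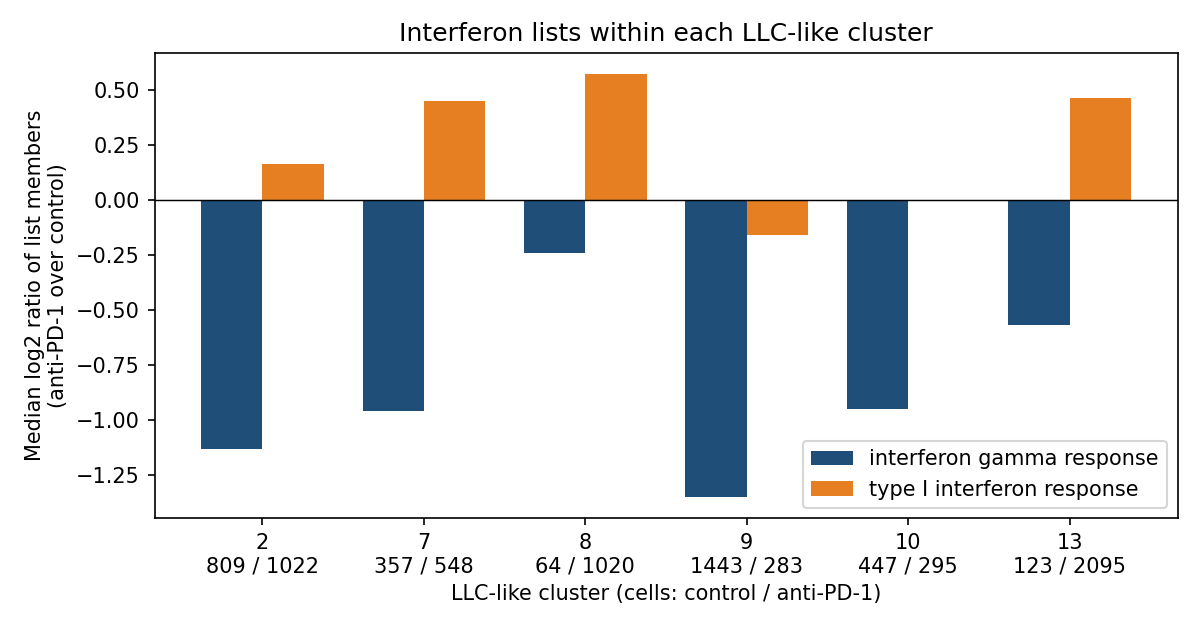
Bars give the median log2 ratio (anti-PD-1 over control) of 2 gene lists within each LLC-like cluster; cell numbers per library stand below each cluster. The interferon gamma list is below 0 in each of the 6 clusters, from -1.35 in cluster 9 to -0.24 in cluster 8.

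Hypoxia and glycolysis genes were lower in anti-PD-1 LLC-like cells, with a median of -0.49 and 31 of 33 members below the median gene. Ankrd37 stood at -1.32, Eno2 at -1.01 and Bnip3 at -0.96. Vegfa, a vessel growth factor, was at 81.4 CPM in control and 44.4 in anti-PD-1, and Ldha, which makes lactate, at 1691 and 1112. Within single clusters the list's median lay between -0.40 and -0.04, each nearer 0 than over all LLC-like cells. With the LLC-like clusters weighted equally it was -0.19, with Ankrd37 at -0.81, Eno2 at -0.45, Bnip3 at -0.33, Ldha at -0.32 and Vegfa at -0.25, and with each cell named by its own marker score Vegfa stood at 0.00. Immediate early and heat shock genes had a median of -0.56, led by Hspa1a at -1.74, Hspa1b at -1.55 and Atf3 at -1.53. Within single clusters its median was nearer 0, between -0.34 and -0.20 in clusters 2, 7, 8, 10 and 13, and in cluster 9 it was 0.41. With the clusters weighted equally the median was -0.13, Hspa1b stood at -0.46 and Atf3 at -0.40, and in cluster 9 Atf3 was at 0.64. In the unfolded protein response list the median was 0.18, yet Trib3 (-2.11), Atf3, Chac1 (-0.98) and Asns (-0.79), which respond to amino acid stress, were the members farthest from 0; with each cell named by its own marker score Trib3 stood at 0.78, Chac1 at 0.61 and Asns at -0.36, and the list's median was 0.43. Autophagy and lysosome genes were higher, with a median of 0.26, 22 of 30 members above the median gene, and Gaa at 0.78; with at least 1000 genes per cell the median was 0.13. The proliferation genes Mki67 and Top2a stood at 0.11 and -0.20, and the G2 and M phase list at a median of -0.06.

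Among all 11593 measured genes of LLC-like cells, 121 were over 2-fold higher and 238 over 2-fold lower in anti-PD-1, and without clusters 2 and 13 the counts were 72 and 170. With genes over 5 times higher in another class left out, 63 were higher and 63 lower. The highest by the naming rule were Gria3, a glutamate receptor subunit (11.7 and 35.1 CPM, log2 ratio 1.59, 1.48 to 1.71), the basement membrane collagen Col4a6 (1.51), Gask1b (1.46), the kinase gene Dmpk (1.31) and the collagen Col4a5 (1.28). Lower values among them were those of Atp13a4 (1.20), Stox2 (1.07), Clu (1.07) and Inka2 (1.05). Dkk2, a secreted Wnt pathway regulator, was at 257 and 585 CPM (1.19, 1.16 to 1.21). The lowest, besides the interferon genes above, were the cytokine Il24 (30.8 and 2.91 CPM, -3.40, -3.60 to -3.21), Trib3 (-2.11), Aldh1l2 (-1.48), Apol6 (-1.42) and Plaat3 (-1.39). Hbb-bt, a globin gene of red blood cells, was at -3.54 and was also among the lowest genes of macrophage-like and monocyte-like cells. Il24 and Trib3 were among the genes that led cluster 9, Dkk2 led cluster 8, and Gria3, Dmpk and Atp13a4 were among those that led cluster 13. Within single clusters the log2 ratios lay between -3.77 and -1.72 for Il24, which had too few UMIs in cluster 13, between 0.81 and 1.38 for Dkk2, 0.38 and 1.66 for Gria3, and 0.17 and 1.22 for Dmpk. In cluster 10 Aldh1l2 stood at 0.82, Chac1 at 0.62, Trib3 at 0.38, Asns at 0.15 and Atp13a4 at -0.19, each opposite to its value over all LLC-like cells. Without cluster 13 Stox2 stood at 0.69, Dmpk at 0.50 and Atp13a4 at 0.43, and with the clusters weighted equally Inka2 stood at 0.66 and Aldh1l2 at -0.27. With each cell named by its own marker score Aldh1l2 stood at -0.19, Gria3 at 0.99 and Gask1b at 2.26, and over clusters 2, 7 and 10 Gask1b stood at 0.89.

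On mm10, Il24 lies on chromosome 1 from 130882074 to 130887454, Iigp1 on chromosome 18 from 60376027 to 60392634 and Ido1 on chromosome 8 from 24584136 to 24597009. Dkk2 lies on chromosome 3 from 132085292 to 132180304, Gria3 on chromosome X from 41400854 to 41678601 and Cd274 on chromosome 19 from 29367455 to 29388095. Col4a6 (141165403 to 141474076) and Col4a5 (141475385 to 141689234) are neighbours on chromosome X. All are annotated as protein-coding, and the counts are per gene, without exon or UTR positions.

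Macrophage-like cells of the anti-PD-1 library were lower in MHC class II genes, which present antigen to CD4 T cells. The median log2 ratio was -2.22, with 7 of 8 members below the median gene. Ciita, the master regulator of these genes, stood at -2.81, H2-Eb1 at -2.30, H2-Aa at -2.28 and H2-Ab1 at -2.26. The members not over 5 times higher in another class numbered 2, with a median of -0.40, and the ratio of the list's summed UMIs was -0.69. The interferon gamma list had a median of -1.05, with 24 of 27 members below the median gene. The T cell attractant Cxcl9 was at 295 CPM in control and 49.0 in anti-PD-1 (-2.59, -2.83 to -2.35), Cd274 at 472 and 146 CPM (-1.69, -1.84 to -1.55), and Irf1 stood at -1.60. At resolution 0.5 the MHC class II median was -1.10, with H2-Eb1 at -1.36, H2-Ab1 at -1.24, H2-Aa at -1.21 and Ciita at -1.19, and the interferon gamma median was -0.68, with Irf1 at -1.06. No monocyte-like class was named at that resolution, so the macrophage-like class there may hold monocyte-like cells as well. Its make-up was not examined. With at least 1000 genes per cell Cxcl9 stood at -1.5, and with each cell named by its own marker score Cd274 stood at -1.11. The median gene of this class lay at -0.11, so values near 0 lie above it.

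Hypoxia genes were lower in macrophage-like cells too, with a median of -0.75 and 27 of 29 members below the median gene. Vegfa was at 457 and 122 CPM (-1.91), Egln3 stood at -1.68 and Hilpda at -1.56. Arg1, an arginine-degrading enzyme of suppressive macrophages, was at 502 and 216 CPM (-1.21), and Il10 at 58.7 and 9.85 (-2.57). With each library clustered alone the hypoxia median was -0.47, Vegfa stood at -0.96, Hilpda at -0.74 and Egln3 at -0.50, and with each cell named by its own marker score Il10 stood at -1.5. The list of suppressive macrophage genes as a whole had a median of 0.35, with 17 of 23 members above the median gene, among them Lyve1 (1.59) and Folr2 (1.30), which led cluster 4. With at least 1000 genes per cell that median was -0.04, Lyve1 stood at 0.32 and Folr2 at 0.77, and without cluster 3 the median was 0.11. The highest genes were Sel1l3 (2.45, 2.02 to 2.90), B3gnt7 (2.29), Qpct (2.02), the transferrin receptor Tfrc (1.98, 1.72 to 2.26) and Npl (1.85). Tfrc stood at 0.46 with each cell named by its own marker score, and with at least 1000 genes per cell Npl stood at 0.64 and B3gnt7 at 1.51. The globins Hbb-bt, Hba-a2 and Hbb-bs were among the lowest, at -3.75, -3.14 and -3.06. Of 8385 genes, 63 were over 2-fold higher and 168 over 2-fold lower. The lower ones numbered 86 with genes over 5 times higher in another class left out. At resolution 0.5, where the class may hold monocyte-like cells, they numbered 100. Cluster 3, led by Hspa1a, Mmp12 and Arg1, held 347 control and 183 anti-PD-1 cells of this class, and cluster 4 held 366 and 514. Without cluster 3 the MHC class II median was -2.75 and the hypoxia median -0.49. With its cells counted as not macrophage-like but kept in the total, the share difference was 1.10 percentage points instead of -1.09.

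Monocyte-like cells showed a split between the interferon lists. The interferon gamma median was -0.46, with 19 of 27 members below the median gene, while the type I interferon median was 0.48, with 27 of 27 above. At resolution 2 the interferon gamma median was -0.19, and with each library clustered alone the type I median was 0.26. Ifit3 was at 164 and 414 CPM (1.34, 1.17 to 1.5), Ifit1 at 55.3 and 135 (1.28) and Usp18 stood at 0.93. Cxcl9 was at 319 and 66.6 CPM (-2.26), Gbp8 at -1.90, Nos2 at -2.48 and Irf1 at -0.77, while Cxcl10, which answers both interferon types, stood at 0.48 (0.41 to 0.55). Cd274 was at -0.94 and Pdcd1lg2, which encodes the other PD-1 ligand, at -1.70. Usp18 stood at 0.35 with at least 1000 genes per cell, Cxcl9 at -1.18 with all deposited barcodes, Irf1 at -1.33 without cells over 3 times the class's median UMI count and -0.50 at resolution 2, and Pdcd1lg2 at -1.11 with each cell named by its own marker score. Cxcl10 stood at -2.03 with at least 1000 genes per cell. The MHC class II median was -0.51, with 7 of 8 members below the median gene. It was 1.03 when cells needed at least 1000 genes and 0.19 when each cell was named by its own marker score.

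Hypoxia genes were lower in monocyte-like cells, with a median of -0.51, Vegfa at -1.07 and Arg1 at -1.32 (396 and 159 CPM). Cholesterol synthesis genes were higher, with a median of 0.51, 18 of 20 members above the median gene, Sqle at 0.93 and Hmgcs1 at 0.74. The highest single genes, besides Ifit3 and Ifit1, were the lipase Lipg (20.1 and 176 CPM, 3.13, 2.71 to 3.59), Ifit1bl1 (1.89) and Fcrls (1.36). Hbb-bt, Hba-a2 and Hbb-bs were the lowest, at -5.07, -4.36 and -4.11. With at least 1000 genes per cell Hba-a2 stood at -2.0 and Hbb-bs at -2.68, and with each cell named by its own marker score Arg1 stood at -2.44, Sqle at 0.57 and Hmgcs1 at 0.44. Of 7654 genes, 22 were over 2-fold higher and 52 over 2-fold lower, and 23 were lower with genes over 5 times higher in another class left out. With at least 1000 genes per cell 7 were higher and 5 lower.

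**Figure D3:**
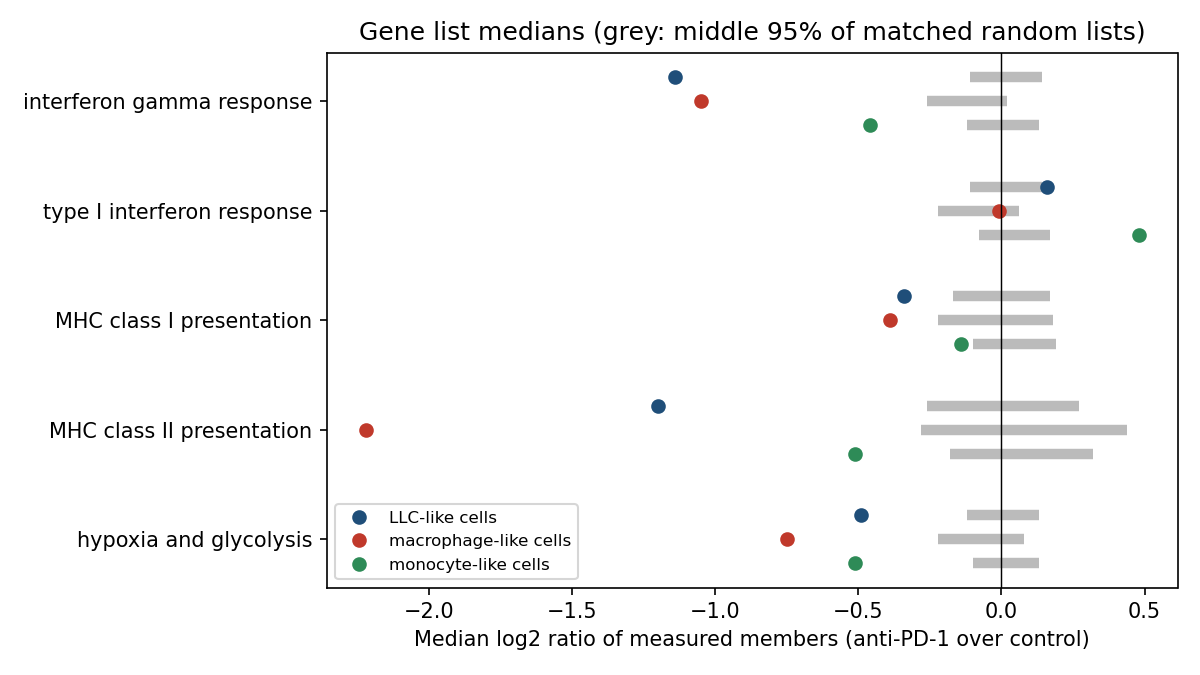
Points give the median log2 ratio (anti-PD-1 over control) of 5 gene lists in 3 cell classes, and grey bars the middle 95% of medians of matched random lists. The interferon gamma list lies at -1.14, -1.05 and -0.46 in LLC-like, macrophage-like and monocyte-like cells, and the type I list at 0.16, -0.01 and 0.48.

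T cell-like cells of the anti-PD-1 library held less Cd8a, the coreceptor of cytotoxic T cells, at 314 CPM in control and 68.7 in anti-PD-1 (-2.19, -2.56 to -1.84). Pdcd1, which encodes PD-1, was at 271 and 66.8 CPM (-2.02, -2.39 to -1.66). Cd4, the coreceptor of helper T cells, was at 23.2 and 58.5 CPM (1.34, 0.77 to 1.92), from 46 and 63 UMIs. The T cell exhaustion list had a median of -1.14, with 12 of 13 members below the median gene, Lag3 at -3.07, Rgs16 at -2.79 and Tox at -2.58. Over the 263 control and 121 anti-PD-1 cells that could be thinned to 1000 UMIs the list's median was -0.22. The minimum of 100 UMIs was applied again after thinning, so the members behind that value can differ. Ifng was at 46.8 and 15.8 CPM (-1.57, -2.41 to -0.81), and Ctla4 at -0.20 (-0.47 to 0.07), with values from -2.25 to 0.33 over the ways of processing. With all deposited barcodes, less those marked when Scrublet was run again, Cd4 stood at -0.70, Cd8a at -4.21, Pdcd1 at -4.07 and Ifng at -3.53. The exhaustion median was then -2.40, with Lag3 at -5.05, Tox at -4.90 and Rgs16 at -4.20. The cell filter and the doublet removal cannot be told apart as the source of this shift. Over genes with at least 300 UMIs that median was -0.26. With thinned cells Pdcd1 stood at -1.30 and Ifng at -0.88, and with each cell named by its own marker score Ifng stood at -3.28 and Cd4 at 0.86. Cells with over 3 times the class's median UMI count held 79.6% of the class's UMIs in control and 84.8% in anti-PD-1, and multiplets among them were not removed; without them Cd8a stood at -1.83 and Pdcd1 at -1.46. Both genes were among those that led the cluster named T cell-like. In NK cell-like cells Gzmb, a killing protease, was at 6005 and 9392 CPM (0.65, 0.57 to 0.72), while Gzmg stood at -4.86 and Gzmf at -3.58; these genes led the cluster of this class. Cells with over 3 times the class's median UMI count held 55.1% of its UMIs in control and 14.9% in anti-PD-1, so the sums rest on deep cells to a different extent. Without them Gzmb stood at 0.87, Gzmg at -4.13 and Gzmf at -2.95, and with each cell named by its own marker score Gzmb stood at 0.00.

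In the smaller classes the interferon gamma median was -1.87 in fibroblast-like, -0.53 in endothelial-like, -0.33 in dendritic cell-like, -0.33 in T cell-like, -0.22 in neutrophil-like and 0.21 in NK cell-like cells. The type I interferon median was 0.70 in NK cell-like, 0.40 in neutrophil-like, 0.35 in dendritic cell-like, 0.30 in T cell-like, 0.07 in endothelial-like and -0.69 in fibroblast-like cells. Here too cells with over 3 times the class's median UMI count held much of the UMIs, and multiplets among them were not removed. Their part in control and anti-PD-1 was 72.5% and 71.1% in neutrophil-like and 64.3% and 62.7% in endothelial-like cells. It was 56.8% and 43.0% in fibroblast-like and 51.2% and 50.4% in dendritic cell-like cells. Over the ways of processing that gave a value, the interferon gamma median lay between -1.94 and -1.16 in fibroblast-like, -1.12 and -0.27 in endothelial-like and -1.09 and -0.20 in neutrophil-like cells. It took both signs in T cell-like (-1.16 to 0.24), dendritic cell-like (-0.41 to 0.08) and NK cell-like cells (-0.28 to 0.45). The type I median lay between 0.18 and 0.89 in NK cell-like and 0.13 and 1.02 in dendritic cell-like cells, and took both signs in neutrophil-like (-1.07 to 0.50), T cell-like (-0.50 to 0.68), fibroblast-like (-0.92 to 0.05) and endothelial-like cells (-0.07 to 0.35).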

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

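The values within single clusters were chosen only after the result was seen. The mitochondrially encoded genes lay on opposite sides in LLC-like and monocyte-like cells. Their median log2 ratio was 0.39 in LLC-like cells and -0.28 in monocyte-like cells, each outside the middle 95% of matched lists. Within single LLC-like clusters the median lay between 0.06, in cluster 9, where 6 of 13 members were below the median gene, and 0.36, so each was nearer 0 than over all LLC-like cells, whose clusters the libraries fill differently. In monocyte-like cells the median was -0.10 at resolution 2. The difference between the classes was not tested, since each group has 1 library.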

How the results depend on the processing

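The interferon gamma median of LLC-like, macrophage-like and monocyte-like cells stayed below 0 in every setting that gave a value, from -1.17 to -0.29, -1.44 to -0.68 and -0.76 to -0.19. The hypoxia median stayed below 0 in these classes, and the T cell share was lower in anti-PD-1 wherever a T cell-like class was named, by -3.87 to -1.65 percentage points. No T cell-like or NK cell-like class was named with at least 1000 genes or at resolution 0.5, nor a neutrophil-like one in the former or a monocyte-like one in the latter. Of 4420 values under an alternative, 3213 stayed within their interval, 1135 moved and 72 reversed. A change of sign counted as reversed only where the main value was far enough from 0. For a gene that was a log2 ratio at least 0.5 from 0, for a list at least 0.1, each with its interval off 0. For a share it was a difference beyond the counting error. Other changes of sign counted as moved or as within their interval, such as Cxcl10 in monocyte-like cells, at -2.03 with at least 1000 genes. The share differences of LLC-like, macrophage-like, monocyte-like, fibroblast-like and NK cell-like cells did not keep their direction; for fibroblast-like cells the range was -0.46 to 21.63 percentage points, and for NK cell-like cells -0.01 to 1.48. Keeping 1 more cell reclustered the data, and a cluster made mostly of cluster 13 cells then stayed unnamed, as at resolution 2 and with at least 1000 genes; elsewhere the cause was not tested. Cells over 3 times the class median, the Scrublet score limit of 0.2, named cells only, members or genes by their level in other classes, cluster weighting, shared clusters, cluster 0 counted as LLC-like, and leaving out clusters 13, 2 with 13, and 3 were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The 177 values that follow are all that reversed by this rule and, of those that moved beyond their interval (a count by over 1.5 times), only shares, gene counts and the interferon, MHC and hypoxia lists of LLC-like, macrophage-like and monocyte-like cells. Other values that moved are not listed here, also where their sign changed. Shares are in percentage points, list intervals come from resampled members, and classes are given without "-like". Where single clusters were left out, their cells stayed in the total for shares. With all deposited barcodes, share differences were LLC 10.47, macrophage -3.92, endothelial -0.55. For neutrophil the log2 ratios were type I interferon -0.36. For T the log2 ratios were type I interferon -0.50, Cd4 -0.70. Genes numbered monocyte 34 lower. With cells of at least 1000 genes, share differences were LLC -7.84, macrophage 3.06, monocyte -0.28. For LLC the log2 ratios were interferon gamma -0.83, type I interferon 0.44, hypoxia -0.34. For macrophage the log2 ratios were MHC class II -2.64, type I interferon 0.15, hypoxia -0.57. For monocyte the log2 ratios were MHC class I 0.15, MHC class II 1.03. Genes numbered LLC 63 higher, macrophage 30 higher, monocyte 7 higher and 5 lower. With the 1 doublet kept, share differences were LLC -0.91, macrophage 0.04. LLC log2 ratios were interferon gamma -0.89, type I interferon 0.38, S phase 0.01. Macrophage log2 ratios were MHC class II -2.85, type I interferon 0.13, hypoxia -0.53. Neutrophil log2 ratios were type I interferon -0.49. For NK the log2 ratios were Cxcl10 1.29. Genes numbered LLC 63 higher. With resolution 0.5, where the macrophage class may hold monocyte-like cells, share differences were macrophage 0.73. For macrophage the log2 ratios were interferon gamma -0.68, type I interferon 0.26. Genes numbered macrophage 100 lower. With resolution 2, share differences were LLC -4.32, macrophage 0.01, monocyte 0.83. For LLC the log2 ratios were interferon gamma -0.84, type I interferon 0.40. Macrophage log2 ratios were MHC class II -2.76, type I interferon 0.15, hypoxia -0.60. Monocyte log2 ratios were MHC class I 0.05. T log2 ratios were MHC class I 0.22, interferon gamma 0.24. Genes numbered LLC 65 higher. With each library clustered alone, share differences were macrophage -0.19, monocyte 2.86, T -3.34, NK 1.48. For macrophage the log2 ratios were MHC class II -2.97, hypoxia -0.47. For monocyte the log2 ratios were type I interferon 0.26, DNA repair 0.02. For neutrophil the log2 ratios were type I interferon -1.07. NK log2 ratios were MHC class II -0.04, interferon gamma -0.16, Ctla4 0.84, Cxcl10 0.48, Vegfa -0.11. With cells named by their own score, share differences were LLC -0.26, macrophage 1.69, monocyte 0.17, neutrophil -0.39, T -1.65, fibroblast 21.63. LLC log2 ratios were MHC class I 0.08, interferon gamma -0.29, type I interferon 0.57, TGF-beta response 0.16, macrophage inflammatory 0.03, angiogenesis 0.00, Cd274 0.24, Chac1 0.61, Id3 0.19, Nos2 1.53, Trib3 0.78, Vegfa 0.00. Macrophage log2 ratios were type I interferon 0.35, hypoxia -0.56, p53 targets 0.08, cholesterol synthesis -0.00. Monocyte log2 ratios were MHC class II 0.19. Neutrophil log2 ratios were type I interferon -0.14. For NK the log2 ratios were MHC class II -0.24, interferon gamma -0.20, Cxcl10 2.32, H2-K1 -0.25. For dendritic the log2 ratios were interferon gamma 0.08. For fibroblast the log2 ratios were type I interferon 0.05. Genes numbered LLC 143 lower, monocyte 59 higher and 86 lower. With median-of-ratios scaling, for macrophage the log2 ratios were type I interferon 0.10, hypoxia -0.64. With cells weighted equally, macrophage log2 ratios were DNA repair 0.01. For monocyte the log2 ratios were growth factor and MAPK output 0.00. For T the log2 ratios were MHC class I 0.19, interferon gamma 0.06. NK log2 ratios were MHC class II -0.13, interferon gamma -0.23. With thinned cells, for macrophage the log2 ratios were TGF-beta response 0.06, growth factor and MAPK output 0.11. T log2 ratios were MHC class I 0.10, interferon gamma 0.12. For NK the log2 ratios were Vegfa -0.01. With a minimum of 30 UMIs, genes numbered LLC 197 higher and 390 lower, macrophage 128 higher and 343 lower, monocyte 72 higher and 172 lower. With a minimum of 300 UMIs, genes numbered LLC 75 higher and 142 lower, macrophage 90 lower, monocyte 13 higher and 25 lower. With summed UMIs of a list, for LLC the log2 ratios were MHC class I -0.17, interferon gamma -0.89. Macrophage log2 ratios were MHC class II -0.69, type I interferon 0.09, TNF and NF-kB response 0.21. With a 1.5-fold limit, genes numbered LLC 587 higher and 635 lower, macrophage 281 higher and 758 lower, monocyte 188 higher and 371 lower. With a 3-fold limit, genes numbered LLC 20 higher and 74 lower, macrophage 17 higher and 50 lower, monocyte 4 higher and 19 lower. Without cells over 3 times the class median UMI count, share differences were macrophage -2.06. For macrophage the log2 ratios were MHC class II -2.41. For T the log2 ratios were MHC class I 0.22, interferon gamma 0.24. NK log2 ratios were interferon gamma -0.28, Vegfa -0.10. Removing cells with a Scrublet score over 0.2, T log2 ratios were MHC class I 0.00. Among named cells only, share differences were LLC 11.04, macrophage -3.43, monocyte -0.20, neutrophil -1.79, T -3.87, endothelial -1.40. For list members not over 5 times higher in another class, macrophage log2 ratios were neutrophil and suppressor 0.04. For genes not over 5 times higher in another class, genes numbered LLC 63 higher and 63 lower, macrophage 86 lower, monocyte 23 lower. Weighting each LLC-like cluster equally, LLC log2 ratios were interferon gamma -0.94, type I interferon 0.34, hypoxia -0.19, Nos2 0.36. Over clusters 2, 7 and 10 alone, for LLC the log2 ratios were interferon gamma -0.76, type I interferon 0.58. Genes numbered LLC 53 higher and 112 lower. Without cluster 13, share differences were LLC -3.54. LLC log2 ratios were interferon gamma -0.86, type I interferon 0.42, hypoxia -0.35. Genes numbered LLC 61 higher. Without clusters 2 and 13, share differences were LLC -4.75. For LLC the log2 ratios were interferon gamma -0.81, type I interferon 0.49, S phase 0.02. Genes numbered LLC 72 higher. Without cluster 3, share differences were macrophage 1.10. For macrophage the log2 ratios were MHC class II -2.75, type I interferon 0.10, hypoxia -0.49. At this depth classes under 200 cells per library give wide intervals.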

Other observations

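Of the tests reported here, those on members by their level in other classes, on single clusters and on the Myc target list after removing the GC and length trend were chosen only after the result was seen. Thinning was planned, and only the bound its values were held to was written after. For the share of genes on the same side in monocyte-like cells, the reading as undecided was also chosen after its genes were seen.

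Oxidative phosphorylation genes of the nuclear genome had a median log2 ratio of -0.27 in LLC-like cells, with 44 of 48 members below the median gene, and -0.27 in monocyte-like cells. The Myc target and ribosome biogenesis list stood at -0.29 and -0.30, and all 28 measured members lay below the median gene in LLC-like cells. Over the ways of processing, the Myc target median lay between -0.38 and -0.15 in LLC-like and -0.58 and -0.09 in monocyte-like cells, and the oxidative phosphorylation median between -0.52 and -0.18 in LLC-like cells. TGF-beta response genes had a median of -0.24 in LLC-like cells, which was 0.16 with each cell named by its own marker score, with Id3 at -1.62 (0.19 under that naming) and Pmepa1 at -1.12. The NRF2 list stood at -0.38 in monocyte-like cells, with Hmox1 at -1.24 (-0.04 with at least 1000 genes per cell).

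The first pattern is the lower interferon gamma list in LLC-like cells. RNA of other cell types as the whole cause is argued against by the 13 members not over 5 times higher in another class, whose median was -1.09. A different mix of clusters as the whole cause is argued against by clusters 2, 7 and 10, whose highest median was -0.95, although cluster 8 stood at -0.24 and clusters 2, 7 and 10 pooled at -0.76. With each cell named by its own marker score the median over LLC-like cells was -0.29. The clusters were made from the same counts, and cluster 7 was led by interferon-induced genes. A different mix of cell states within clusters therefore stays open. Ifng over all cells had a log2 ratio of -0.96 (-1.29 to -0.64, 239 and 125 UMIs), so less interferon gamma in the sampled tumour is a candidate explanation. With 1 library per group, treatment, animal, preparation and collection time cannot be told apart as its source.

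The second pattern is the lower oxidative phosphorylation and Myc target lists in LLC-like and monocyte-like cells. In LLC-like cells thinned to 5000 UMIs the medians were -0.29 (-0.33 to -0.25) for oxidative phosphorylation and -0.26 (-0.37 to -0.20) for the Myc targets. Thinning weights the kept cells equally but leaves each cell's expected proportions as they were. These values therefore argue against the weight of deep cells as the whole cause. They cannot decide on a bias tied to depth, which stays open. In monocyte-like cells thinned to 1000 UMIs the medians were -0.23 (-0.35 to -0.11) and -0.09 (-0.37 to 0.04). The minimum of 100 UMIs, applied again, left 29 and 18 members there against 45 and 26 before. Both intervals reach above the bound of -0.15 written for LLC-like cells. Depth and the changed members cannot be told apart there, so depth stays open for both lists. GC content and length were those of each gene's longest transcript. For the Myc target list, these as the whole cause are argued against by its median of -0.26 (-0.33 to -0.16) in LLC-like cells after removing that trend. The oxidative phosphorylation median was then -0.15 (-0.23 to -0.10) in LLC-like cells and -0.10 in monocyte-like cells. For this list GC content or length cannot be told apart from another cause at this spread. The sequences that probes bind were not examined, so a bias of the probes stays open for both lists. A difference of treatment or of animals stays open and was not tested.

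The third pattern is the different clusters that LLC-like cells of each library fill. Genes beyond 2-fold in LLC-like cells, measured in monocyte-like cells and not over 5 times higher in another class than in either, numbered 9, and 9 of 9 (100%, 66.4 to 100) lay on the same side in monocyte-like cells, which meets the share of at least 80% that a shift shared by all cells was said beforehand to give. All 9 were lower, 7 of them belong to the interferon gamma list and another is the globin gene Hbb-bt, and the interval reaches below 80%, so they say little about the genes that part the clusters. A shift shared by all cells of a library therefore cannot be told apart from a response shared by tumour and myeloid cells. A difference of treatment or of animals stays open and was not tested.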
